A study of Zea mays with 6 samples.

How the data were processed

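Binding of the maize transcription factor ZmNAC24 was measured by DAP-seq (DNA affinity purification sequencing), in which a protein made in vitro is fixed to beads, incubated with a library of naked genomic DNA, and the DNA that stays bound is sequenced. Per the labels, DNA came from primary roots of the inbred line B73 germinated at 28 °C over 2 days without light, 20 µg of it was sheared, and 1 µg of the library was offered to each protein for 1 h. The beads were washed 6 times, and the eluted DNA was amplified over 20 PCR cycles and sequenced in paired reads of 150 bp. NAC24 carried a HALO tag, and GFP with the same tag served as the negative control. Each protein was used in 3 libraries, and per the series' design text the DNA came from separate roots and was shared between the proteins.

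The deposited data used here were a single peak list in 2 versions, a table with annotation and an interval file. Per the submitters' processing notes, positions refer to B73 RefGen v4. The aligner, the peak caller, its filters, the use made of the GFP-HALO libraries and any pooling of replicates were not given in the sources used here. The name of the table contains the number 2, and whether this refers to replicate 2 is likewise not given. The authors' table lists for each peak its position, centre and width, a peak shape score, a p-value, and the nearest gene with its distance on either side. The deposited score and the deposited p-value are the same measurement on 2 scales, since every p-value equalled the upper tail of a standard normal distribution at the score with a largest difference of 3.40e-16. Per the file headers it is a p-value with no adjustment named, and the highest in the table was 0.0500. Scores are the authors' and were used only within this list, to describe, rank, filter or compare its peaks. The table held 0 columns of values per library, so read depth is unknown, replicates could not be compared, and no level in the GFP-HALO libraries could be set beside a NAC24-HALO peak.

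The columns that the authors named for the 5′ and 3′ gene were found to mean the side with lower and with higher coordinates, because the lower-side gene had the smaller number in 1077 of 1077 peaks with both. Strand is therefore not used here, and the distance to the nearer edge of a gene took the place of the distance to the transcription start. Distances ran from the edge of the peak, since all peaks next to the same gene gave a single gene edge for 236 of 236 genes with several peaks, and a distance of 0 means overlap. Exons, introns and untranslated regions were not told apart. The interval file held 1133 intervals against 1132 peaks in the table. All 1132 were matched at an overlap of 1 bp and also at 50% reciprocal overlap, 1108 with identical edges and 24 with edges shifted by at most 2 bp. The interval without a table row lay on chromosome 9 at 57398571 to 57398742, 439 bp from the nearest table peak. The table was used for all counts.

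Of the 1293 genes listed beside peaks, 9 carried a symbol, and the other 1284 were identifiers. None of these identifiers occurred in the RefSeq gene table for the assembly Zm-B73-REFERENCE-NAM-5.0, which held all 9 symbols. That table is of another build and was used for names only. The genes to be named were fixed before the data were examined, as those at the 20 peaks of highest score, every aquaporin and NAC gene with a peak, up to 10 genes with the most peaks, and up to 4 members of each further list. Because the table pairs few identifiers with names, most of these genes are given by position and only a few identifiers are printed. The genes with symbols outside this rule were named after their values were seen, and 1 gene is not reported here. The 22 gene lists were also fixed beforehand, and were matched to symbols alone, without descriptions and without a test of enrichment. Genes with the most peaks were counted over both sides of each peak.

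Shares carry exact binomial (Clopper-Pearson) 95% intervals. For peaks between a pair of genes, the number within 1 kb of a gene edge was set against uniform placement of each peak in its own gap, with 100000 resamples, and the ratio of observed to expected carries a bootstrap interval over gaps with 2000 rounds. Median scores were compared by permutation with 100000 resamples unless stated otherwise, two-sided. Peak counts on the 10 chromosomes were compared with chromosome length by a chi-square statistic with 100000 Monte Carlo resamples, taking the end of the last peak as the length, since no genome of this build was used. The smallest p that these resamples can give is 1e-05. Single chromosomes and chromosome ends were tested with two-sided binomial tests, with Benjamini-Hochberg adjustment over the 10 chromosomes. These tests treat neighbouring peaks as independent, and all intervals cover counting error only. After the data had been seen, peaks within 10 kb of each other, edge to edge, were joined into loci. A locus with 1 peak is called isolated, and one with at least 3 peaks a group. The number of peaks with a neighbour was set against 1000 rounds in which each chromosome kept its number of peaks and their positions were drawn at random up to the end of its last peak, uniformly or with weights from the density of loci along it. Results were then repeated on isolated peaks and on 1 peak per locus, and isolated peaks were compared with groups by permutation over loci, adjusted over the 4 measures compared. Where 1 peak was drawn per group, each draw was tested with 2000 resamples. The spacing of peaks in groups was tested with 100 rounds of random shifts. The threshold on peak strength, the distance to a gene and the expectation for the chromosomes were varied as well.

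The tests were checked on simulated peaks. With uniform placement the test of distance called 4 of 100 simulated sets of 904 peaks, and with peaks moved next to genes 100 of 100. The corresponding counts were 4 and 95 of 100 for the chromosomes with 1105 peaks, and 7 and 98 of 100 for scores with 1132 peaks. The planted effects on distance and score were larger than those seen in the list, with a median ratio of 3.41 for distance, so smaller effects could be missed. Simulated peaks were drawn independently of each other, so these counts do not cover a list with grouped peaks. Searches for 5 NAC motifs and for enriched 6-base words, random placement relative to annotated genes over the whole genome, reassignment to the nearest gene start and the position of the summit needed sequence or annotation not used here. Differential binding needed values per library, and was not analysed here. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.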

Results

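ZmNAC24 belongs to the NAC family of plant transcription factors, and the series asked which sites of the maize genome it binds, with aquaporin genes as one interest named by the submitters. DAP-seq was run on primary root DNA of the inbred line B73 with 3 NAC24-HALO and 3 GFP-HALO libraries. The peak list compared here holds a single value per peak, so no value has a replicate error. Positions are on B73 RefGen v4.

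The list held 1132 peaks, of which 1105 lay on the 10 chromosomes, 25 on 10 unplaced contigs and 2 on the plastid genome. Peaks were narrow, with a median width of 218 bp (range 132 to 330). The median peak shape score was 2.51, with quartiles of 1.97 and 3.43 and a maximum of 22.2. The list thus had a long weak end: 535 peaks (47.3%) had an unadjusted p of at most 0.005, 360 (31.8%) of at most 0.001, and 46 (4.06%) of at most 1e-10.

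The highest peak scores lay at a pair of intergenic loci. On chromosome 2, 5 peaks lay between 157585024 and 157593105, 2366 to 10192 bp from Zm00001d005077, and 4 of the 6 highest scores of the list fell among them. The strongest peak of all, at 157592040 to 157592279, scored 22.2 (p = 3.09e-109 in the authors' deposited table) and lay 9382 bp from that gene. On chromosome 1, the peak at 197011891 to 197012127 scored 21.8 and belonged to a locus of 6 peaks, with the nearer gene 34230 bp away. The 20 strongest peaks, with scores of 8.77 to 22.2, came from 13 loci. Of these peaks 1 overlapped a gene, 4 more lay within 1 kb of one, 12 lay more than 5 kb from the nearest listed gene, and 4 were on unplaced contigs, where a gene is listed on a single side.

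Those of the 20 that overlapped a gene or lay within 1 kb of one were all isolated peaks. A peak with a score of 10.1 on chromosome 2 (19852593 to 19852813) started 4 bp from Zm00001d002707. The peak overlapping Zm00001d048775 on chromosome 4 (5329471 to 5329689) scored 8.77. On chromosome 1, peaks starting at 64840558 and 286082897 scored 13.9 and 13.1 and lay 801 and 679 bp from a gene, and on chromosome 3 the peak starting at 186400696 scored 10.2 at 319 bp from a gene.

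Among the named genes, 1 aquaporin was listed. NIP3-1, of the NIP subfamily of these water and solute channels, was the lower-side neighbour of a peak on chromosome 1 (227514691 to 227514912) with a score of 2.38 (p = 0.00871 in the authors' deposited table). This peak lay 61611 bp from NIP3-1 and 24878 bp from the gene on its other side. Within 5 kb of a peak, 0 aquaporin genes were named. The other 21 lists, among them NAC and further transcription factor families and hormone, cell wall, transport and stress genes, matched 0 of the symbols. Most of these lists were written as words of gene descriptions, so the expansin EXPB1 and the ribosomal protein gene rps16 escaped the wall-loosening and ribosomal lists. As 9 of 1293 genes carried a symbol, the counts set no limit on members among the identifiers.

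Of the genes with symbols, peaks overlapped CFM3, ATPA and the plastid gene rps16. CFM3, a CRM-domain protein of chloroplast intron splicing, held an isolated peak on chromosome 2 (235053994 to 235054211) with a score of 3.46. ATPA, which encodes the alpha subunit of an ATP synthase, was overlapped by 3 peaks on chromosome 3, and 1 more peak lay 220 bp from it. These belonged to a run of 10 peaks from 74898002 to 74908459 with scores of 1.91 to 5.32, the highest of them inside ATPA at 74907619 to 74907854 (p = 5.20e-08 in the authors' deposited table). The peak in rps16, a gene of the small ribosomal subunit, lay at 3768 to 3987 of the plastid genome and scored 1.66, near the weakest value of the list, 1.64. The symbol ATPA also occurs on the plastid genome in the RefSeq table.

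**Figure D1:**
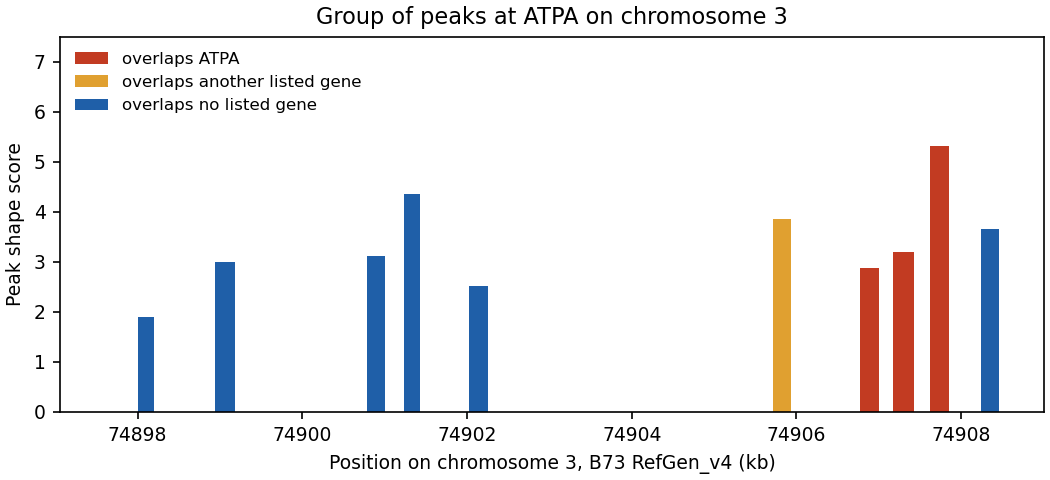
Peaks at ATPA on chromosome 3. The x axis gives the position in kb and the y axis the peak shape score of the authors, each bar spans 1 peak at its true width, and colour shows whether it overlaps ATPA, another listed gene or none. The 10 peaks span 74898002 to 74908459, with the highest score of 5.32 inside ATPA.

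Further named genes lay farther from their peaks. PCNA, the sliding clamp of DNA replication, was 3380 bp from a peak on chromosome 5 (220302595 to 220302812, score 1.93) that itself overlapped another gene. The expansin gene EXPB1, from a family of wall-loosening proteins, was 11766 bp from a peak on chromosome 9 (120098774 to 120098994, score 3.14). FEA2, a receptor-like protein that restrains shoot meristem size, was 100365 bp from its peak on chromosome 4 (136665291 to 136665505, score 1.86), and CAF1 on chromosome 7 was 173568 bp from a peak with a score of 1.77.

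Where peaks lay relative to genes was the next question of the design. Peaks overlapped 170 genes, with 195 of 1132 peaks (17.2%, 95% interval 15.1 to 19.6) inside or across a gene. A further 116 peaks (10.2%, 8.54 to 12.2) lay within 1 kb of a gene edge, and 601 (53.1%) lay more than 5 kb from any listed gene. More than 50 kb away lay 159 of the 1132 peaks (14.0%). Peaks that overlapped no gene were a median of 12228 bp from the nearest gene (n = 937). The overlap share rose to 23.8% among the 593 isolated peaks, and the share within 1 kb to 15.3%.

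Peaks between genes were nevertheless closer to gene edges than uniform placement in the same gaps gives. Of these peaks (n = 904), 116 lay within 1 kb of a gene against 69.2 expected, a ratio of 1.68 (95% interval 1.39 to 2.01, p = 1e-05, the smallest the resamples can give). Within 2 kb the ratio was 1.70 and within 10 kb it was 1.29. Among 447 isolated peaks, 91 lay within 1 kb against 45.8 expected, a ratio of 1.99 (1.61 to 2.44). For peaks in groups (n = 356) the counts were 22 and 20.1, a ratio of 1.10 with an interval of 0.665 to 1.55 (p = 0.71). Within 10 kb the ratio for groups (n = 356) was 1.15 (p = 0.00313 with peaks taken as independent), but its interval over gaps, 0.941 to 1.43, included 1.

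**Figure D2:**
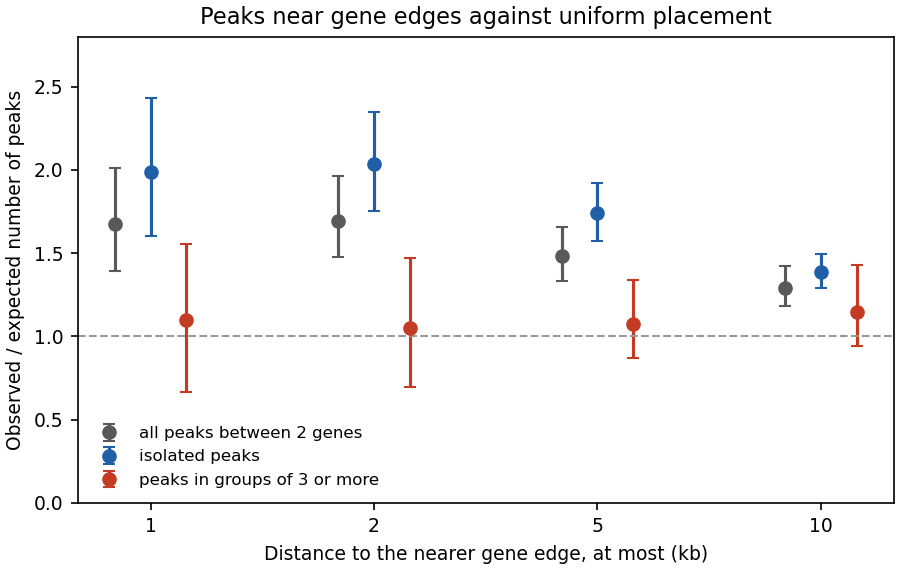
Peaks near gene edges against uniform placement between genes. The x axis gives the largest distance counted, in kb, and the y axis the ratio of observed to expected peaks, points are ratios for all peaks, isolated peaks and peaks in groups of at least 3, and bars are 95% bootstrap intervals over gaps. The ratio within 1 kb is 1.99 for isolated peaks and 1.10 for groups, and the dashed line marks a ratio of 1.

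Peaks beside a gene, without overlapping one, were not detectably stronger or weaker than all other peaks. The median score was 2.46 for the 116 peaks within 1 kb of a gene edge and 2.52 for the other 1016 (permutation p = 0.61). These 1016 include the 195 peaks that overlap a gene, so this is not a comparison of close with distant peaks. For the 195 peaks that overlapped a gene the median was 2.37, against 2.53 for the remaining peaks (permutation p = 0.133).

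Peaks often lay side by side. Within 10 kb of another peak lay 539 of 1132 (47.6%, 44.7 to 50.6). This interval takes peaks as independent, although neighbours count together, so it is too narrow. On the chromosomes 516 peaks had such a neighbour, while 1000 random placements along the same chromosomes gave a median of 12 and at most 32. With placement weighted by the density of loci along each chromosome, the median was 14 and the maximum 38. Joined at this distance the list made 713 loci, namely 593 isolated peaks, 58 pairs and 62 groups with 423 peaks. Neighbouring peaks within a locus were a median of 580 bp apart (quartiles 239 and 1224.5). The largest group held 29 peaks on chromosome 2 from 79918069 to 79945104, and 26 peaks lay on chromosome 7 from 179705006 to 179725933. The gene listed for the most peaks, Zm00001d046083 on chromosome 9, was a neighbour of 35. The 10 genes with the most peaks were each listed for 17 to 35, at any distance. Some of them flank the same peaks, as do the genes on either side of the 26 peaks on chromosome 7, so they stand for fewer separate places.

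Groups differed from isolated peaks in their place relative to genes. Per locus, a mean of 14.96% of the peaks of a group overlapped a gene or lay within 2 kb, against 49.6% of isolated peaks (62 and 593 loci, permutation p = 1e-05, adjusted 4e-05). Overlap alone was 8.73% against 23.8% (permutation p = 0.00621, adjusted 0.0124). The 58 pairs were left out of these tests. Of their 116 peaks, 9.48% overlapped a gene and 69.8% lay more than 5 kb from one. Among the 423 peaks in groups these shares were 10.2% and 67.8%, so lying away from genes was not particular to groups. The mean score per locus was higher in groups, at 3.40 against 2.92 (permutation p = 0.0240, adjusted 0.0320). With 1 peak drawn at random per group, so that single peaks stood on both sides, the median was 2.71 against 2.41, a difference that passed the test in 40 of 100 draws (median permutation p = 0.0940). The difference in width did not pass the test (permutation p = 0.22). All these tests took loci as independent, although some groups lay close together, such as 4 on chromosome 9 from 61921559 to 61991347. Isolated peaks also leaned to the chromosome ends, with 305 of 589 (51.8%, 47.7 to 55.9) in the outermost 20% at either end, together 40% of the length (binomial p = 9.13e-09). Of the peaks in groups 126 of 410 (30.7%) lay there. This count gives weight to groups with many peaks, such as 6 groups with 67 peaks between 60 and 100 Mb on chromosome 9. The density of genes along the chromosomes was not taken into account in either share.

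**Figure D3:**
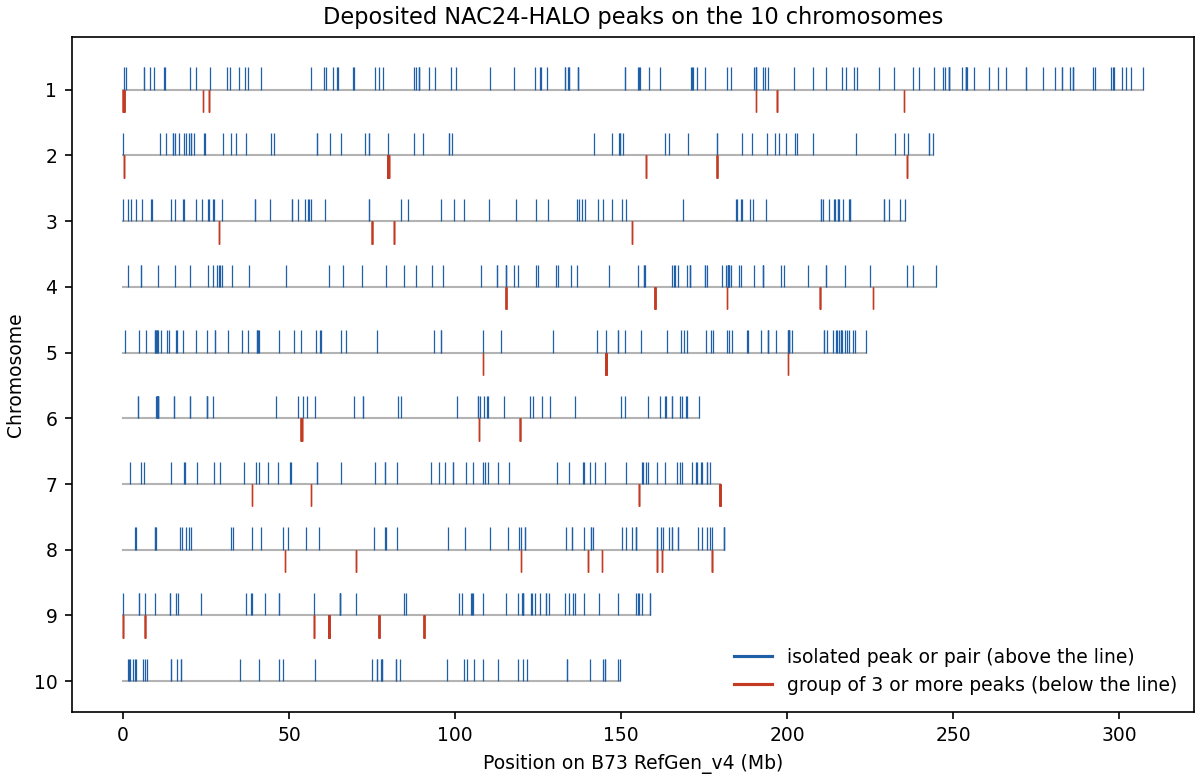
Peaks along the 10 chromosomes. The x axis gives the position in Mb and each row is a chromosome drawn to the end of its last peak, with isolated peaks and pairs as ticks above the line and peaks in groups of at least 3 as ticks below it. Chromosome 9 carries 144 peaks, many of them at a few places, and chromosome 10 carries 45.

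Chromosomes did not hold peaks in proportion to their length (chi-square 64.4, Monte Carlo p = 1e-05). Chromosome 9 had 144 peaks where its length gives 83.6, a ratio of 1.72 (binomial p adjusted over chromosomes 2.80e-09), and chromosome 10 had 45 where 78.8 were expected, a ratio of 0.571 (binomial p adjusted 1.54e-04). On chromosome 9, 67 peaks fell in 6 groups between 60 and 100 Mb, 35 of them in 4 groups from 61921559 to 61991347. Counted as isolated peaks, the chromosomes did not differ detectably (chi-square 10.9, Monte Carlo p = 0.282), and the same held for 1 peak per locus (11.7, p = 0.233).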

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

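The alternatives on isolated peaks, on 1 peak per locus or gap, on neighbouring peaks and on scores per locus were chosen after the data were seen. Of 44 alternatives, 23 kept their direction and side of the threshold or stayed within the interval, 4 no longer passed the test, 15 moved and 2 changed sign. In the settings varied here, the ratio of peaks near a gene edge ranged from 1.49 to 1.99 and passed the test in each. These were within 2 and 5 kb, from the peak centre, and within 1 kb on the 566 and the 283 strongest peaks, on isolated peaks and on 1 peak per gap. Other settings lay outside this range, among them 1.29 for all peaks within 10 kb and 2.04 for isolated peaks within 2 kb. For groups within 1 kb the ratio was 1.10 and did not pass. The median score of peaks within 1 kb of a gene but not overlapping one, minus that of all other peaks, passed the test in no setting. This difference turned from -0.06 to 0.17 on the 566 strongest peaks and to 0.17 on isolated peaks, and the cause was not tested. The score difference between groups and isolated peaks was 0.45 by the median over loci (permutation p = 0.00509) and 0.35 without the highest 5% of loci on both sides (permutation p = 0.00939), although both set averages over a group beside single peaks. With 1 peak drawn per group it was 0.30 and no longer passed. Without the 3 groups of highest mean score it was 0.090, a fall that leaving out high values on 1 side brings by construction. The share overlapping a gene rose to 23.8% on isolated peaks and 21.6% on 1 peak per locus. The share beside a gene became 18.1% up to 2 kb, 29.7% up to 5 kb, 15.3% on isolated peaks and 13.0% on 1 peak per locus. The chromosome chi-square fell to 10.9 and 11.7 in these same settings, each with fewer peaks. At a p 10 times stricter than the weakest peak, 535 peaks were left. The named aquaporin count was 0 among the 566 strongest peaks, among the 283 strongest, within 1 kb and within 5 kb. Peaks with a neighbour made up 42.7% at 2 kb, 52.4% at 50 kb, and at 10 kb 44.5% of the 566 strongest and 34.6% of the 283 strongest, where fewer peaks are left to be neighbours. Whether these shares moved was judged by an interval that is too narrow for them. For the other moved values the cause was not tested, apart from wider distances taking in more peaks.

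No paired analysis was possible because the peak list holds no values per library. For the same reason differential binding with its normalizations, filters, pseudocounts and left-out replicates was not run. Motifs, 6-base words and the nearest gene start were not run without sequence and annotation of this build, and no summit was used. Depth per library is unknown, so what it limits could not be measured.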

Other observations

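All tests of explanations here were chosen after the patterns were seen, and the one on repeated spacing was set down before its result was known. On 10 unplaced contigs, 25 peaks had a median score of 2.73 and a maximum of 12.7, against a median of 2.51 on the chromosomes, a difference that was not tested, and 4 of them were isolated. On the plastid genome 2 peaks were listed, with a median score of 2.02. In 2 further places groups of at least 15 peaks lay on chromosome 9, with 17 peaks from 77039738 to 77055163 and 15 from 90533121 to 90556792.

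The grouping of peaks was the first pattern weighed. Near-exact copies of the same part of a single stretch of DNA, with every peak listed, would share the spacing of their peaks. If the 45 groups with at least 4 peaks were such copies, most of their 990 pairs would do so. Yet 13 pairs shared 4 or more centres within 15 bp, against a median of 10 (6 to 17) after shifting the centres at random by up to 150 bp (n = 45 groups, p = 0.248 by these shifts). If each group were a regular, fully listed tandem repeat of 1 unit, most of the 299 spacings that could recur within groups would do so. Instead 35 did (28 after shifting, 18 to 36.5, n = 62 groups, p = 0.0792 by these shifts). Both values argue against such near-exact copies and regular repeats as the whole cause among the groups tested. In 1 simulated set each, 6 planted copies gave 24 shared pairs and 6 planted repeats gave 46 recurring spacings, above the values seen. The planted sets were near exact and lacked no peak, so these counts are a best case. Fewer, diverged or partly listed copies and less regular repeats therefore stay open, as do copies among the smaller groups. Copies of different parts of a longer stretch need not share any spacing, so this test cannot decide on them. Organelle DNA inserted in the chromosomes may also give runs of peaks. Of the 62 groups, the one at ATPA alone lists a gene with a symbol, and this symbol also occurs on the plastid genome. The other groups could not be looked up. Inserted organelle DNA cannot be told apart from other sources, because nearly all listed genes lack names and no sequence was used. No biological explanation was tested, since no GFP-HALO values could be compared.

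The closeness of peaks to genes was weighed next. Chance calls among the weaker peaks could dilute or create it. The stronger part of the isolated peaks, above their median score of 2.41, gave a ratio of 1.91 (1.45 to 2.52) within 1 kb and the weaker part 2.09 (1.51 to 2.84). The closeness was thus not confined to the weaker part, but the stronger part can also hold chance calls, so their share in it stays unknown. Groups that happen to lie by a gene are argued against by the ratio of 1.99 among isolated peaks. Whether reads map more readily next to genes than in repeats farther away was not tested and remains a candidate explanation, as does binding itself, and the GFP-HALO libraries that could separate them were not analysed here.

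The excess on chromosome 9 may rest on a few groups with many peaks. Counted as loci, it held 59 against 53.0 expected, a ratio of 1.11 (0.855 to 1.42), below the ratio of 1.72 for its peaks. What gives those groups so many peaks is the question left open above.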
